A study of Sulfolobus acidocaldarius with 2 samples.

How the data were processed

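RNA sequencing was used to measure transcript levels in 2 cultures of the type strain of Sulfolobus acidocaldarius, a thermoacidophilic archaeon. Per the labels' protocols, both cultures grew at 77 °C and pH 3.3 in Brock's mineral medium with 0.1% (w/v) tryptone and 0.005% (w/v) yeast extract. The sugar-rich culture also received 0.2% (w/v) glucose. Cells were taken in early exponential phase, total RNA was treated with DNase I, and libraries were made with an Illumina TruSeq RNA kit. The labels give 1 library per medium, so there was no replicate of either condition and no spread between cultures could be measured. Whether ribosomal RNA was depleted, the read length and the strandedness are not given in the sources used here.

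The authors deposited, for each library, raw read counts per gene, described per the file headers as counted reads per gene. BWA and SAMtools are named in the submitters' processing notes, without versions; the program that counted reads is not given in the sources used here. The authors also deposited RPKM values, which per the file headers are read counts normalised to gene length and to the number of mapped reads. Dividing the counts back out of the RPKM gave the summed deposited counts of each library, so the authors' RPKM are relative to reads in the listed genes. Gene length in the deposited files is the end minus the start position, in all 2224 genes, which is 1 base shorter than the gene. The deposited GC percent of each gene was used as a covariate only. Both files list the same 2224 loci with coordinates on the chromosome, and every library total given here is the sum over those loci. None of the loci matched to the reference table was an RNA gene there. The type of the 43 loci that were not matched is not known, and they could include RNA genes.

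Locus tags were matched to a RefSeq gene table of assembly ASM1228v1, whose chromosome sequence is the one the files name. Of the 2224 loci, 2181 matched and 43 did not; 3 matched loci are annotated as pseudogenes and 324 loci carry a gene symbol. Start or end differed from that table in 230 matched loci. Coordinates given here are those of the deposited files, 1-based. The other genes are named by their older locus tags (Saci_ numbers) or, where there was none, by the newer tag. The table gives no product names and no strand, and whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Gene sequences were not used here, so reads shared between near-identical genes could not be assessed, and 1035 of the 2224 loci overlap a neighbour by at least 1 base.

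From the counts, CPM (counts scaled to a common total over the listed genes) were computed for each library. The plan had been to scale over protein-coding genes; all 2224 loci were used, including the 43 that were not matched and the 3 pseudogenes. The measure compared is the log2 ratio of sugar-rich over sugar-free CPM after adding a pseudocount of 1, which pulls the ratios of weak genes towards 0. Fold values are ratios of CPM without the pseudocount. Genes with a mean CPM of at least 10 over both libraries were kept, which left 2086 genes. With 1 library per medium no test across genes was made and no p-value is given. A gene is called at least 2-fold higher or lower when its log2 ratio is at least 1 or at most -1. For single genes, an exact (Clopper-Pearson) 95% interval of the ratio was computed from the counts. These intervals cover counting error only. No molecular identifiers are mentioned in the labels or headers, so reads were not taken as independent molecules, and differences between cultures, RNA preparations and libraries are not in the intervals. The lowest count of any gene was 4 in the sugar-free and 6 in the sugar-rich library, and 10 reads correspond to 0.243 and 0.312 CPM.

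Gene lists were set against random lists: a list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched in 10 bins of mean CPM, for lists with at least 3 kept members. The percentile describes these 2 libraries and is not a p-value. Random lists scatter over the chromosome, whereas members of several lists lie side by side, so for 10 blocks of neighbours the median was also placed among all blocks of as many neighbouring genes in which most genes passed the filter. That comparison was added after the data were seen. Of 37 lists, 31 were fixed before the data were examined, by locus tag or by words in product names. Because the gene table gives symbols only, members of the lists defined by product name were taken from gene symbols. By then a few rows of each file had been looked at to learn their layout, but no ratio had been computed. These lists therefore held only the few members with a symbol. For 6 lists (amino acid and peptide transport, peptidases, ATP synthase, transposases, toxin-antitoxin genes, ion transport) no member could be taken this way, and these are not analysed here. Another 6 lists were added once the symbols, but not the ratios, had been seen. The pentose transporter list had under 3 members and has no percentile, so 30 lists have one.

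The genes named were set by a rule written at the same time as the first lists: the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio, up to 4 members per list with the largest absolute log2 ratio, the 5 most abundant genes of each library, and the members of the maltooligosaccharide and pentose transport clusters. Other genes named, most of which stand beside these on the chromosome or in the same list, were chosen after their values were seen. Alternatives were other scalings of the libraries (median of ratios, TMM and upper quartile), pseudocounts of 0.1 and 5, no filter or a mean CPM of at least 50, thresholds of 1.5-fold and 4-fold, 5 bins or no matching for the random lists and, added later, the deposited RPKM in place of CPM. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 for the TMM and upper-quartile factors only.

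The procedure was tested on simulated Poisson counts with the real genes and library sizes, in which 200 genes were changed by 3-fold or 4-fold. All 50 genes in each of the 4 sets (3-fold and 4-fold, higher and lower) passed the 2-fold threshold, counted without the filter on mean CPM. None of the unchanged genes that passed the filter was called, and 95.0% of the true ratios lay inside their counting intervals, over 2083 genes. Poisson counts hold no difference between cultures, so the simulation says nothing about that error.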

Results

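With glucose in the medium, 41 genes of Sulfolobus acidocaldarius had at least 2-fold higher and 29 at least 2-fold lower transcript levels than without it, out of 2086 genes compared between 1 library of each medium. The run of genes around sat, of sulfate assimilation, was 2.81-fold to 3.64-fold higher with glucose, and the respiratory genes cbsA to soxC (Saci_1861) were 2.11-fold to 2.52-fold higher, although 3 of these 4 weakly expressed genes lay below the threshold with a pseudocount of 5. The pentose transporter genes xylF and xylH, the phosphoenolpyruvate synthase gene ppsA and 3 genes of the SoxM oxidase cluster were 2.02-fold to 2.82-fold lower. The 4 genes of glucose breakdown that could be listed by symbol, gapN, eno, kdgK and pyk, lay within 2-fold.

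Transcript levels had been measured by RNA sequencing in 1 culture on tryptone and yeast extract (sugar-free) and 1 with 0.2% (w/v) glucose added to that medium (sugar-rich), and the comparison asks how added sugar alters them. The sugar-free library held 41198949 reads in 2224 genes and the sugar-rich library 32090767. Every gene had reads in both libraries, and the median count per gene was 6131 in the sugar-free and 5098 in the sugar-rich library. At this depth counting error was small for most genes, and the difference between cultures was not measured. All differences are between these 2 libraries and have no replicate check. Coordinates are those of the deposited files on the chromosome, and each named locus is a whole annotated gene.

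Most of the transcriptome was alike in both media. The most abundant transcript in each was slaA, the gene of the main surface-layer protein that coats the cell. It took 7.79% of reads in the sugar-free library (exact 95% binomial interval 7.78 to 7.80) and 8.01% in the sugar-rich library (8.00 to 8.02), a difference whose sign turned with the other scalings of the libraries. Its neighbour Saci_2354, the thermosome gene thsB, which encodes a chaperonin subunit, and tes, known for joining lipid tails into membrane-spanning tetraethers, were among the 5 most abundant genes of both libraries. Saci_0054 completed that group in the sugar-free library and tuf, a translation elongation factor gene, in the sugar-rich library. None of these 6 genes differed by 2-fold; Saci_0054 had the largest difference, with 12732 CPM without and 9003 CPM with glucose. Across the 2086 genes kept, 86.9% differed by less than 1.5-fold, the median log2 ratio was 0.06, and Pearson's r between the libraries on the log2 scale was 0.975 across genes, which are not independent replicates.

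The 41 higher and 29 lower genes made up 3.36% of the genes kept. For 36 of the 41 and 26 of the 29, the counting interval also lay beyond 2-fold. At a 4-fold threshold, 6 genes were higher and 3 lower. Only 12 of these 70 genes carry a symbol in the gene table, so most are given here by locus tag, and 29 overlap a neighbouring gene, whose reads could not be told apart. Of the 70 genes, 46 stood next to another gene called in the same direction, in 17 runs of 2 to 6 neighbours. In 10000 random orders of the genes the mean was 2.33 such genes and the highest 14.

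**Figure D1:**
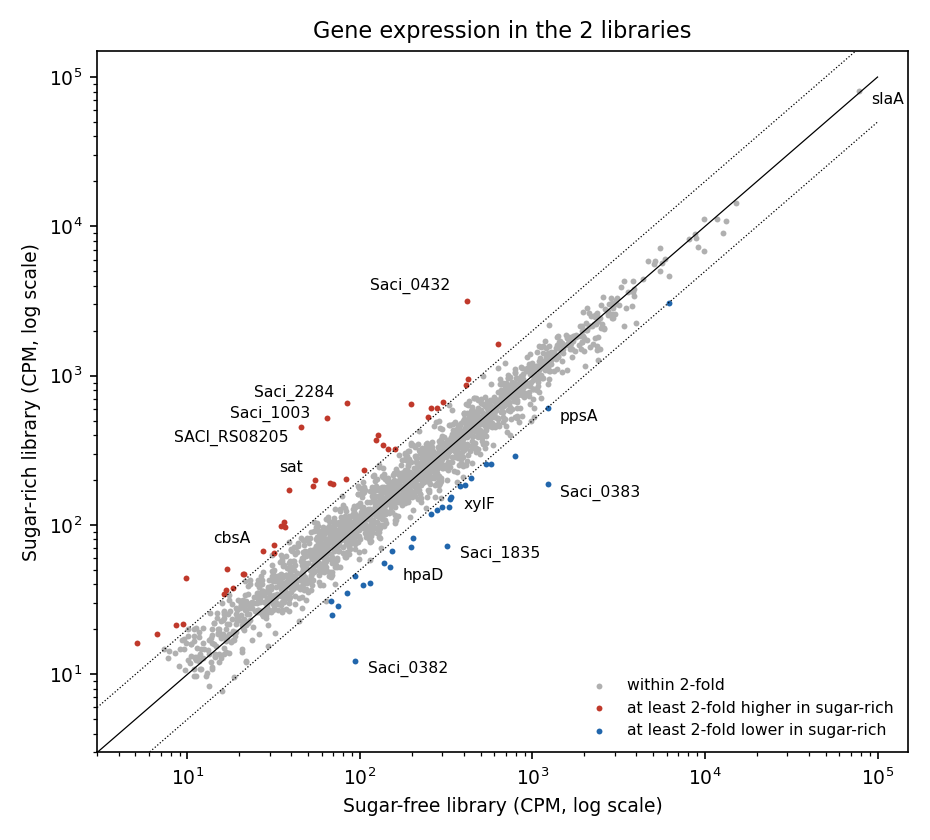
Expression of the 2086 genes kept, in CPM on log scales, in the sugar-free (x axis) and sugar-rich (y axis) library; each point is 1 gene in 1 library per medium, the solid line marks equal CPM and the dotted lines 2-fold. Most points lie between the dotted lines, 41 genes (red) are at least 2-fold higher and 29 (blue) at least 2-fold lower with glucose.

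The highest ratios with glucose were in genes without a symbol. SACI_RS08205, a short gene at 1477012 to 1477200 on the chromosome, had 45.4 CPM without and 452 CPM with glucose, 9.96-fold higher (counting interval 9.49 to 10.5). Saci_1003 (803952 to 805004) was 8.09-fold higher (7.77 to 8.43). The neighbours Saci_2283 and Saci_2284 (2128235 to 2129314) were 4.44-fold and 7.77-fold higher, and the neighbours Saci_0432 and Saci_0433 (369796 to 371498) 7.61-fold and 4.50-fold. Saci_0432 was the most abundant of these, with 419 CPM without and 3184 CPM with glucose.

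A run of 5 genes around sat, which encodes the sulfate adenylyltransferase that activates sulfate for assimilation, was higher with glucose throughout. The gene sat itself (2041202 to 2042437) had 55.0 CPM without and 200.4 CPM with glucose, 3.64-fold higher (3.47 to 3.82). Its neighbours Saci_2202, Saci_2201, Saci_2204 and Saci_2200 were 3.44-fold, 3.03-fold, 3.02-fold and 2.81-fold higher. Saci_2200 was chosen after its value was seen, as were Saci_2197 and Saci_2198 just upstream in coordinates, which were 2.53-fold and 2.57-fold higher. Saci_2320 and Saci_2321 (2166873 to 2170987), which overlap by 4 bp, were 3.26-fold and 3.14-fold higher.

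The lowest ratios were in Saci_0382 and Saci_0383 (329597 to 331356), which were 7.61-fold (6.86 to 8.46) and 6.51-fold (6.34 to 6.69) lower with glucose. The longer gene, Saci_0383, had 1227 CPM without and 188 CPM with glucose. Saci_1835 (1599696 to 1600976) was 4.42-fold lower. The gene hpaD, whose name denotes a ring-cleaving dioxygenase of aromatic compound breakdown, was 2.85-fold lower (2.70 to 3.01), and its neighbour Saci_2294 was 2.49-fold lower. A run of 6 genes, Saci_2228 to Saci_2233 (2070581 to 2076403), was 2.19-fold to 2.72-fold lower, with Saci_2229 at 787 CPM without and 289 CPM with glucose. The remaining genes of the 12 lowest were Saci_1688, Saci_1944 and Saci_1431, which were 2.78-fold, 2.64-fold and 2.48-fold lower, and 3 genes of a respiratory cluster described below.

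Of the central sugar metabolism genes that could be listed by symbol, ppsA was the only one past 2-fold. The gene ppsA, which encodes phosphoenolpyruvate synthase, the enzyme that makes phosphoenolpyruvate from pyruvate, had 1222 CPM without and 606 CPM with glucose, 2.02-fold lower, and its counting interval of 1.98 to 2.05 spans the threshold. The other 4 measured members of the gluconeogenesis and sugar phosphate list, fbp, tpiA, rpiA and hxlB, lay within 2-fold, and fbp, the fructose bisphosphatase gene, had 1798 CPM without and 1808 CPM with glucose. The list's median log2 ratio was 0.01, at percentile 42.7 of random lists, while its mean was -0.12. None of the 4 members of the list for the Entner-Doudoroff pathway, by which this archaeon breaks down glucose, and lower glycolysis was 2-fold different. Their log2 ratios were 0.48 for gapN (non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase), 0.31 for eno (enolase), 0.14 for kdgK (2-keto-3-deoxygluconate kinase) and 0.01 for pyk (pyruvate kinase), whose sign turned with the other scalings of the libraries. The list's median of 0.22 lay at percentile 89.2. Of 6 citric acid cycle, glyoxylate shunt and pyruvate oxidation genes none differed by 2-fold. The one farthest from 0 was porB, named for a pyruvate ferredoxin oxidoreductase subunit, with 2005 CPM without and 1160 CPM with glucose, a log2 ratio of -0.79. The list's median was 0.09 (percentile 78.3) and its mean -0.07. The trehalose and glycogen list (treZ, glgX, treH1, treH2) had log2 ratios from -0.35 to 0.36 and a median of -0.08 at percentile 22.3, and the sign of treH2 turned with other scalings.

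Among sugar uptake genes, the transporter that takes up pentoses was lower with glucose and the maltooligosaccharide cluster was split. The genes xylF and xylH, encoding the substrate-binding and membrane proteins of the pentose ABC transporter (1944229 to 1946514), were 2.18-fold (2.11 to 2.25) and 2.47-fold (2.34 to 2.61) lower with glucose, and the adjoining xylG, the ATPase gene, was 1.89-fold lower (1.80 to 1.99). Only 2 members of the fixed pentose transporter list were found by tag, with a median log2 ratio of -1.20, too few for a percentile. As a block of 3 neighbours, xylG, xylH and xylF had a median of -1.12, at percentile 0.70 of all such blocks. In the list of glycoside hydrolases and sugar transporters, these 3 were joined by bgaS (beta-glycosidase), with a log2 ratio of 0.33, and malA (alpha-glucosidase), with 0.83, and the list's median of -0.91 lay at percentile 0.020. In the cluster Saci_1160 to Saci_1166, none of 7 genes differed by 2-fold. The log2 ratios of malA, Saci_1161, Saci_1162 and Saci_1166 were 0.83, 0.69, 0.50 and 0.40, and those of Saci_1163, Saci_1164 and Saci_1165 were -0.48, -0.58 and -0.32. The cluster's median of 0.40 lay at percentile 96.9 of random lists and at percentile 90.4 of blocks of 7 neighbours. Among random lists it lay above the 95% range with no filter (97.8), a mean CPM of at least 50 (98.79) or no matching (97.95). The mean was 0.15, and the median says little of members that differed in both directions.

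Genes of the aerobic respiratory chain differed in both directions. Of 18 members, 4 were at least 2-fold higher with glucose, 3 at least 2-fold lower and 11 within 2-fold. The list's median of 0.04, with a mean of -0.06, lay at percentile 36.9, which says little of members that differed in both directions. The 4 higher genes are neighbours (1633061 to 1638038): cbsA and cbsB, named for a cytochrome b complex, soxL2, for a Rieske iron-sulfur protein, and soxC (Saci_1861). cbsA had 27.5 CPM without and 66.5 CPM with glucose, 2.42-fold higher (2.25 to 2.60), and cbsB, soxL2 and soxC were 2.11-fold (1.91 to 2.32), 2.52-fold (2.21 to 2.87) and 2.21-fold (2.03 to 2.41) higher. cbsB, soxL2 and soxC (Saci_1861) were chosen after their values were seen. With a pseudocount of 5 their log2 ratios were 0.89, 0.97 and 0.99, below the threshold, and that of cbsB was also below it under each other scaling (0.96 with TMM). All 4 genes had a mean CPM under 50 and were left out by that filter, and they lie between 1500 and 1700 kb, where the median log2 ratio of 144 genes was 0.36. The lower genes lie in the cluster Saci_2258 to Saci_2263, known as the SoxM terminal oxidase complex. Saci_2260, Saci_2261 and Saci_2262 were 2.79-fold, 2.82-fold and 2.57-fold lower, with counting intervals wholly beyond 2-fold, and Saci_2258, Saci_2259 and Saci_2263 had log2 ratios of -0.72, -0.65 and -0.59. Among blocks of as many neighbours, cbsA to soxC lay at percentile 99.5 and Saci_2258 to Saci_2263 at percentile 0.38. The block cbsA to soxC holds only genes called at least 2-fold higher. Its high place was therefore nearly given by that choice and is no separate evidence of a shift. The far more abundant genes of the other oxidase, soxA, soxB and soxC (Saci_2087), had 1010, 1944 and 2307 CPM without and 1102, 2136 and 2469 CPM with glucose. The genes nuoN, nuoI, nuoH and ndhC, named for a NADH dehydrogenase type of complex, had log2 ratios between -0.01 and 0.09, and that of cyoE was 0.05.

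**Figure D2:**
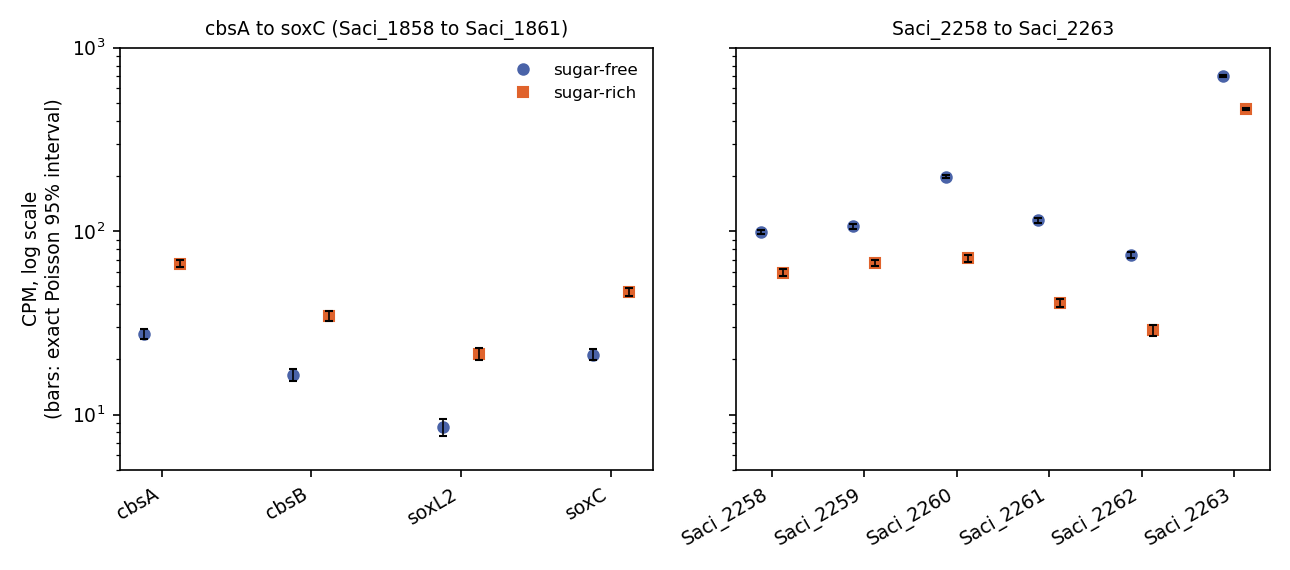
CPM on a log scale of the 4 genes from cbsA to soxC (left) and the 6 genes from Saci_2258 to Saci_2263 (right) in the sugar-free (circles) and sugar-rich (squares) library, with exact Poisson 95% intervals for counting error, 1 library per medium. All 4 genes on the left were higher and all 6 on the right lower with glucose.

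Among surface structures, the genes of the UV-inducible (Ups) pili, which mediate cell aggregation, were higher with glucose. All 5 had ratios above 1, and Saci_1494 was 2.23-fold higher (2.16 to 2.30). upsA, a pilin gene, was 1.93-fold higher, upsF 1.73-fold, upsX 1.60-fold and Saci_1497 1.33-fold. The list's median of 0.78 lay at percentile 99.9 of random lists and at percentile 98.3 of blocks of 5 neighbours. Of the archaeal adhesive (Aap) pili, 4 of 6 fixed tags were in the files. Saci_2314 was 2.22-fold higher, while Saci_2316, Saci_2317 and Saci_2318 had log2 ratios of -0.22, -0.45 and -0.38. The median was -0.30, at percentile 1.90, and the mean, which follows Saci_2314, was 0.03. The list lay inside the 95% range with no filter (2.74), 5 bins (3.205) or no matching (2.66), and as a block of 4 neighbours it lay at percentile 7.54. The archaellum cluster, Saci_1172 to Saci_1178, was weakly expressed, and 5 of its 7 genes passed the filter. Saci_1178 had 63.4 CPM without and 109 CPM with glucose, a log2 ratio of 0.78, and the list's median of 0.24 lay at percentile 63.5.

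The redox list was higher with glucose: all 6 members had ratios above 1, with a median log2 ratio of 0.48 at percentile 99.7. The gene dps, encoding a DNA-protecting, iron-storing protein, was 2.03-fold higher (1.97 to 2.09), and its log2 ratio was 0.94 to 0.97 under the other scalings, below the threshold. The log2 ratios of pdo (protein disulfide oxidoreductase) and trxA (Saci_1823, thioredoxin) were 0.53 and 0.51. dps and trxA (Saci_1823) lie between 1500 and 1700 kb, where the median log2 ratio of all 144 genes was 0.36, against 0.04 elsewhere, and the other 4 members had log2 ratios of 0.24 to 0.53. The chaperone list lay inside the 95% range, with ratios above 1 in 4 and below 1 in 3 members. In it hsp20, a small heat shock protein gene, was 2.12-fold higher (2.08 to 2.16), and the other 6 genes lay within 2-fold, including both thsA genes and thsB at -0.09 to 0.16. The median of 0.16 lay at percentile 91.7.

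The amino acid biosynthesis list was slightly lower with glucose, with 26 of 33 ratios below 1 and none past 2-fold. The median log2 ratio was -0.19, at percentile 0.010, with the lowest values in ilvD (-0.60), argH (-0.58), aroA (-0.49) and hisG (-0.47). The 9 neighbouring genes hisC to hisI are part of that list and lay at percentile 5.55 of such blocks. The purine and pyrimidine list had a median of -0.08 at percentile 6.23, inside the 95% range. Within it pyrB, pyrD, pyrC and pyrI of the pyrimidine pathway had log2 ratios of -0.68, -0.64, -0.57 and -0.54, while the purine genes lay between -0.08 (purE) and 0.27 (purC), both chosen after their values were seen. The remaining members, carA, thyX, carB, pyrH and pyrE, also chosen afterwards, had log2 ratios of -0.35, -0.33, -0.26, -0.13 and -0.08. All 6 genes of the cell division (Cdv) machinery, which is ESCRT-III-like, had ratios below 1. Their log2 ratios lay within a narrow range of -0.34 to -0.10, with a median of -0.23 at percentile 2.23. The list lay inside the 95% range with a mean CPM of at least 50 (2.85), 5 bins (3.24) or no matching (2.58), and its 3 neighbours cdvC to cdvA lay at percentile 13.2 of such blocks.

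Of the 30 lists, 4 had a median below the 95% range of random lists (sugar transporters and hydrolases, amino acid biosynthesis, Cdv and Aap pili) and 2 above it (Ups pili and redox genes). The places of Cdv and Aap pili did not hold in each alternative. That of sugar transporters and hydrolases rests on the neighbours xylF, xylH and xylG, while the hydrolase genes malA and bgaS had ratios above 1. Of these 2, bgaS lies between 1500 and 1700 kb, where the median log2 ratio was 0.36. Random lists of scattered genes vary less than lists of neighbours, so the 5% outside that range by chance does not hold for lists of neighbours. The other fixed lists with a percentile lay inside the 95% range of random lists. The maltooligosaccharide cluster, whose members were split in direction, lay at percentile 96.9. It lay above that range with no filter (97.8), a mean CPM of at least 50 (98.79) or no matching (97.95). The medians were 0.13 for ribosomal proteins (percentile 92.3), 0.00 for aminoacyl-tRNA synthetases (41.8), 0.14 for RNA polymerase genes (77.6), -0.04 for DNA replication and repair (13.3), -0.00 for the proteasome (45.4), -0.14 for isoprenoid and ether lipid synthesis (5.43), 0.00 for acyl-CoA metabolism (28.7), 0.28 for CRISPR-Cas (91.5) and 0.06 for transcriptional regulators (52.2). Of the 6 lists added later, the medians were -0.20 for cut oxidoreductases (percentile 4.83), 0.04 for cobalamin synthesis (44.4), 0.22 for molybdenum cofactor synthesis (71.7), -0.16 for glycine cleavage (11.9), 0.45 for DNA import (93.4) and -0.17 for chromatin proteins (13.0).

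**Figure D3:**
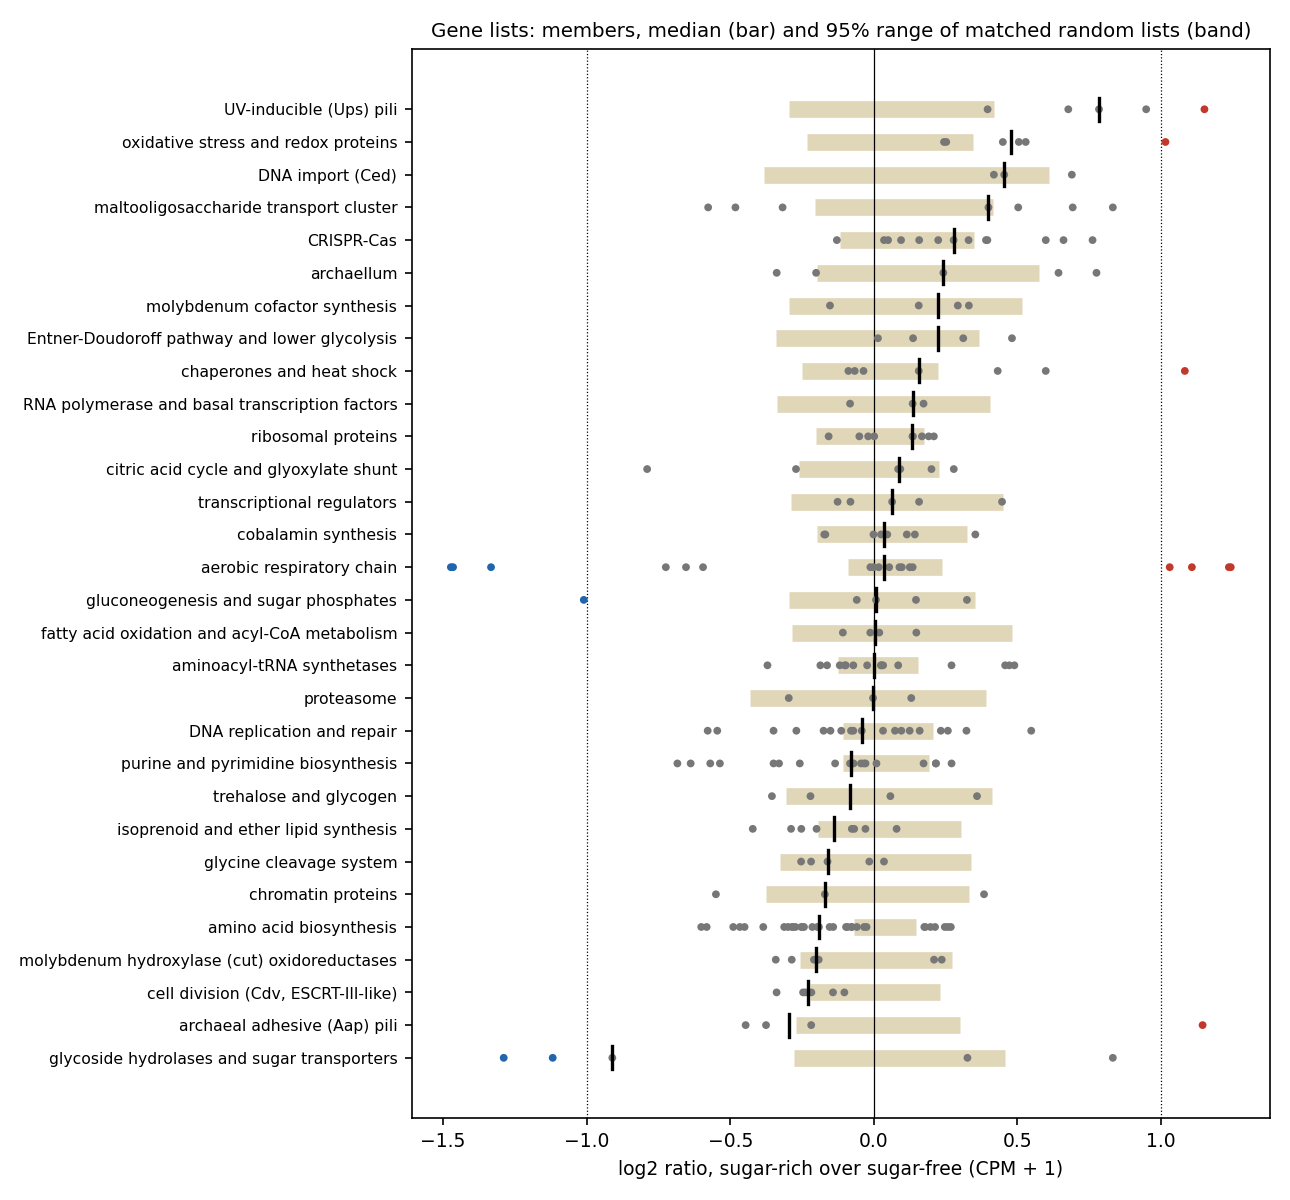
The log2 ratio of sugar-rich over sugar-free CPM (pseudocount 1) for each kept member (points; red and blue at least 2-fold) of the 30 gene lists, with the list's median (bar) and the central 95% of the medians of 10000 matched random lists (band), 1 library per medium. The medians of 4 lists lie below their band and those of 2 above it, with Ups pili highest at 0.78 and the sugar transporter list lowest at -0.91.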

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

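The median log2 ratio moved by 0.05 to 0.07 between the scalings, less than 0.1. Counts of higher genes were 37 under each of the 3 other scalings and lower genes 33 to 36, against 41 and 29. The calls lost with scaling were Saci_0951, Saci_1225, dps and cbsB. Pseudocounts of 0.1 and 5 gave 42 and 32 higher and 31 and 28 lower genes, and the deposited RPKM, an alternative chosen after seeing the data, gave 44 and 30. Without a filter there were 45 and 29, and with a mean CPM of at least 50 there were 28 and 27. With thresholds of 1.5-fold and 4-fold the counts were 179 and 6 higher and 95 and 3 lower, as the thresholds imply. The list percentiles stayed on the same side of the 95% range in 200 comparisons with an alternative and crossed it in 9. Of the scalings, only median of ratios was among these alternatives. It shifts all genes almost alike, so it could hardly move a list's place. Blocks of neighbours were not among them. The maltooligosaccharide cluster lay above it with no filter (97.8), a mean CPM of at least 50 (98.79) and no matching (97.95). The Cdv list lay inside the range with a mean CPM of at least 50 (2.85), 5 bins (3.24) and no matching (2.58), and the Aap pili with no filter (2.74), 5 bins (3.205) and no matching (2.66); the cause was not tested. Of the 145 genes named by the rule, 5 with log2 ratios under 0.06 changed sign with scaling, and 1 of the 32 called ones, dps, lay under 2-fold with the other scalings and a pseudocount of 5. Of the genes chosen after their values were seen, cbsB, soxL2 and soxC (Saci_1861) also lay under 2-fold with a pseudocount of 5 (0.89, 0.97 and 0.99). Counting error left 5 of the 41 higher and 3 of the 29 lower calls with intervals that reach below 2-fold, and no replicate could be left out. No paired analysis was possible because each medium had 1 library.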

Other observations

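The 3 patterns weighed here were noticed in the data and tested on the same data, after medians along the chromosome and correlations of neighbours had been seen. The test of pairs of long genes was chosen after its result was seen. Another difference between the cultures was added as an explanation afterwards and could not be tested, with 1 library per medium. Beyond the lists described above, glpK (Saci_2033), a glycerol kinase gene, was 2.21-fold lower with glucose (counting interval 2.05 to 2.38), with 68.2 CPM without and 30.9 CPM with glucose. The other glpK (Saci_1117) had 144 CPM without and 176 CPM with glucose. The gene Saci_0155, at 6187 CPM without and 3087 CPM with glucose, was the most abundant of the called genes and was 2.00-fold lower, barely past the threshold. The 6 neighbours from pyrD to pyrE had a median log2 ratio of -0.57, at percentile 1.51 of blocks of 6 neighbours, while pyrE alone was at -0.08. These genes were chosen after their values were seen.

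Genes between 1500 and 1700 kb, a range set after seeing the data, had higher ratios with glucose than the rest: the median log2 ratio of 144 genes was 0.36, against 0.04 for the 1942 genes elsewhere, and 76.4% of them lay above the outside median. The 100-kb windows from 1700 to 2000 kb had medians of 0.18, 0.11 and 0.14, and that from 1400 to 1500 kb 0.09. These were also above 0.04, but windows far from the region had similar medians, such as 0.16 from 800 to 900 kb and 0.10 from 900 to 1000 kb. The flanking values therefore do not show whether the region is sharply bounded. Chance order is argued against, since 2 of 10000 orders of shuffled blocks of 10 genes gave a 100-kb window as high as the real highest (0.46). The region's genes are weakly expressed (median of the mean CPM 73.3 against 189 elsewhere). The shift was not confined to the weak ones: the 36 region genes above the overall median RPKM had a median of 0.33, and the 108 below it 0.37. The 36 genes lay at percentile 100 of lists matched on RPKM from outside. The region was chosen for its high ratios, so a high percentile was nearly given and cannot decide on background reads raising weak genes. A trend with GC content, length and abundance explained 3.46% of the variance and left the region's median residual at 0.25. That residual lay at percentile 100 of random lists, a place that the choice of the region also favoured. A difference in DNA copy number may account for the region's higher ratios and stays open. The 10th percentile of ratios was shifted by 0.23 (95% block bootstrap interval -0.05 to 0.39). That interval includes both no shift and the shift of the median, 0.31. An effect of the medium on this region is also open and untested.

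The respiratory clusters had opposite shifts, with medians of 1.17 for cbsA to soxC and -1.03 for Saci_2258 to Saci_2263. After the fit on GC content, length and abundance the medians were 2.15 apart, against 2.20 before, so this fit removed little of the gap. It explained 3.46% of the variance over all genes, so it could hardly have closed a gap this wide. The cbsA cluster was also chosen for its high ratios, so the comparison does not decide on such a trend. The cbsA cluster lies inside the region of higher ratios, and the place of its lowest gene, percentile 99.3 of the region's other 140 genes, was fixed by choosing 4 of the region's 6 higher calls, so a part of the regional shift in this cluster stays open. The other cluster lies outside that region. An effect of glucose is untested and cannot be told apart from another difference between the cultures, with 1 library per medium.

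Neighbouring genes had similar ratios, with Pearson's r of 0.468 across 1997 adjacent pairs of genes, which are not independent. The correlation was 0.748 for 1111 pairs less than 50 bp apart and 0.0475 for 374 pairs at least 200 bp apart, inside the 95% range of shuffled orders, whose upper end is 0.102. The 1111 close pairs include 599 that overlap, with r of 0.780, and close pairs without overlap were not examined apart. The difference between close and distant pairs was 0.700 (95% bootstrap interval 0.602 to 0.794), which shared transcripts could give. This interval and that for long genes below resampled single pairs as if independent. Adjacent pairs can share a gene, so both intervals may be too narrow. Reads counted for both of a pair could also give a correlation that ends with distance, but in 123 pairs of genes of at least 1000 bp, with overlaps of at most 53 bp, r was 0.767 (0.649 to 0.862), which argues against double counting for those pairs; for shorter genes it stays open.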
